A study of Homo sapiens with 58 samples.

How the data were processed

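Messenger RNA was measured in 58 human cell lines labelled as breast cancer, at baseline, with 1 custom Affymetrix array per line. Per the labels, the lines were grown as the vendor recommended without treatment, and total RNA was processed in parallel in well plates, amplified with a NuGEN protocol and labelled with biotin. The deposited values are log2 intensities that the authors made with RMA (background correction, quantile normalization and summary of probes to probe sets) in Affymetrix Power Tools, both without a stated version. Whether the 58 arrays were normalized together is not stated. The table held values from 1.53 to 14.77 for 52377 probe sets. Array medians and the interquartile range of relative log expression were computed as quality measures. The deposited table holds no control probe sets for the ratio of transcript ends, so that measure was not used.

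Of the probe sets, 35184 named 1 gene and were used, 374 named several genes and 16819 named none, and these were left out. The 605 viral probe sets had a median of 3.31 and a 95th percentile of 5.59, and no line exceeded a probe set's own median by more than 1.16, so they served only as a measure of background. Each gene was represented by its probe set with the highest mean, a choice that concerns 8731 of 19798 genes. A gene was detected if it was above the array median in at least 3 units, which held for 14650. Gene order and names were taken from a GRCh38.p14 gene table. The build of the probe set annotation was not stated, so no positions are given. XIST and Y-linked genes were left out of the named genes, and some list members are not reported here.

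The labels define no groups. Lines reported to derive from 1 patient or 1 parental line were averaged, since they are not independent, which gave 50 units (6 sets with 14 lines, and 44 single lines). This grouping rests on textbook knowledge. The grouping, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated otherwise.

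Variable genes were counted by an SD of at least 1. For 30 gene lists, 21 of pathways, identities and chromosomal neighbours and 9 of other cell types, a score was the mean over detected members of the distance from the gene's median. Its SD was tested by permuting each member across units (10000 times, 1-sided) with Benjamini-Hochberg adjustment over lists, and described against 10000 random lists matched on mean level. Relations were given as Pearson r and Spearman rho with 100000 permutations (exact under 10 units), for 28 pairs of 8 scores, for ERBB2 with its 17q12 neighbours and among 9p21 genes, each family adjusted on its own. A measure was taken to form separate clusters if a mixture of 2 components beat 1 component by over 10 BIC units with Ashman's D over 2 and at least 3 units in each, and r was then given only within clusters of at least 6 units. Genes associated with ESR1, ERBB2, CDH1 and MKI67 were found with limma (trend and robust, Benjamini-Hochberg adjusted p under 0.05), with the level of the gene as a continuous term and its cluster as a factor where clusters existed. Lists were tested with camera with a preset and an estimated correlation, adjusted over lists. Line-specific genes exceeded every other unit by at least 3 log2 units, which is 8-fold. Low tumour suppressors were more than 3 median absolute deviations (scaled by 1.4826) and at least 1.5 log2 units below the median. Pairs of lines were compared by the mean r over genes against 100000 assignments of the line names. R 4.3.3, limma 3.58.1, mclust 6.1.1 and Matrix 1.6.5 were used.

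The genes named were every receptor of the list, the 15 most variable genes, the 3 most variable members of each other list, the 10 positive and 10 negative slopes with the smallest adjusted p for each of the 4 fits, the gene with the largest gap in each of the 15 units with the largest gaps, every member of the 17q12, 9p21 and tumour suppressor lists, and the 3 genes that differed most in each set of related or like-named lines, where the pairs within a set of 3 were each listed.

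The alternatives were the mean of probe sets, probe sets marked for cross-hybridisation left out, a second quantile normalization, no filter and a stricter filter on low values, all 58 lines as units, the MDAMB435 set and MT3 left out (reported not to come from breast tumours), the 3 widest arrays left out, array quality as a term, other thresholds, other scalings and another eBayes setting. The steps were tested on simulated data with the spread of each gene. Of 100 planted slopes of 0.5, the ESR1 fit recovered 87, the ERBB2 fit 83, the CDH1 fit 74 and the MKI67 fit 51, and at 0.25 they recovered 56, 48, 37 and 9, with 7, 8, 4 and 3 unchanged genes called. The permutation test found 99 of 100 planted correlations of 0.6 and called 5 of 100 unrelated pairs. The cluster rule found 50 of 100 planted splits and 0 in 100 unsplit measures. All 200 planted line-specific genes were found, but each lay 4 log2 units above the gene's maximum, past the rule of 3, so this outcome was fixed. Genes were simulated independently, so the false calls above do not cover correlated genes.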

Results

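The series holds baseline transcript profiles of 58 human cell lines labelled as breast cancer, each grown without treatment and measured on 1 array. Of these, at least MDAMB435S, M4A4, NM2C5 and MT3 are reported not to come from breast tumours. This list may not be complete, since the labels do not tell tumour lines from others, and no other line was left out on this ground. Labelled RNA was read out with 52377 probe sets, of which 35184 name a single gene, and these cover 19798 genes. No line was measured more than 1 time, so there are no replicates, and the tests below use the spread between lines. The number of arrays limits the precision. Array medians lay between 5.37 and 5.59 on the log2 scale, and the interquartile range of relative log expression, a measure of array quality, lay between 0.45 and 0.64. Lines reported to come from 1 patient or 1 parental line were averaged, which gave 50 units, 44 single lines and 6 averaged sets that hold 14 lines. A set is named here by its lines joined with _ or by the shared part of the name, such as AU565_SKBR3, EFM192 and MDAMB435, the last being MDAMB435S with its derivatives M4A4 and NM2C5. In these units 14650 genes were detected. Highest and lowest values below are those over units unless a line of a set is named, since averaging can hide a more extreme line. The labels give no subtype, so lines are described by the measured levels of genes and no line is assigned to a group.

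Hormone and growth factor receptors, which define the clinical classes of breast cancer, separated the lines by large factors. ESR1, the estrogen receptor, was highest in T47D at 12.73, ZR751 at 12.69 and KPL1 on the log2 scale, and at background in 21 units, where background means levels up to 5.59, the 95th percentile of the viral probe sets. PGR, the progesterone receptor, was above the array median in only 6 units, led by T47D at 11.55 and ZR751 at 11.03. ERBB2, the HER2 receptor, was above the array median in all 50 units and highest in UACC893 at 13.69, HCC1569 at 13.68 and ZR7530. EGFR peaked in MDAMB468 at 13.18 and was at background in 4 units, MFM223 among them. MFM223 had the highest FGFR2, 13.35 against 11.80 in the next unit, CAL51. MDAMB453 had the highest FGFR4, a fibroblast growth factor receptor, at 12.68 against 11.44 in EVSAT, and CAL120 the highest FGFR1 at 10.88. KIT, the stem cell factor receptor, was highest in MT3 at 11.76 and MB157_MDAMB157 at 11.61. ERBB3, the partner of HER2, reached 13.10 in CAL148 and was at background in 6 units, HS739T among them, and ERBB4 was highest in CAL51 at 11.89. PRLR, the prolactin receptor, was highest in T47D at 10.53. MET reached 12.52 and IGF1R 11.62, both in MCF102A, and IGF1R was at background in 2 units, HCC1187 among them. All 13 measured receptors had an SD across units above 1, from 1.47 for ERBB2 to 3.07 for ESR1. Among the lines inside sets, AU565 had 13.70 of ERBB2, MB157 12.28 of KIT and HMT3522S1 12.53 of MET, above the highest units. With the mean of all probe sets of a gene in place of its highest probe set, the SD of ESR1 was 1.80 and that of IGF1R 0.79.

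**Figure D1:**
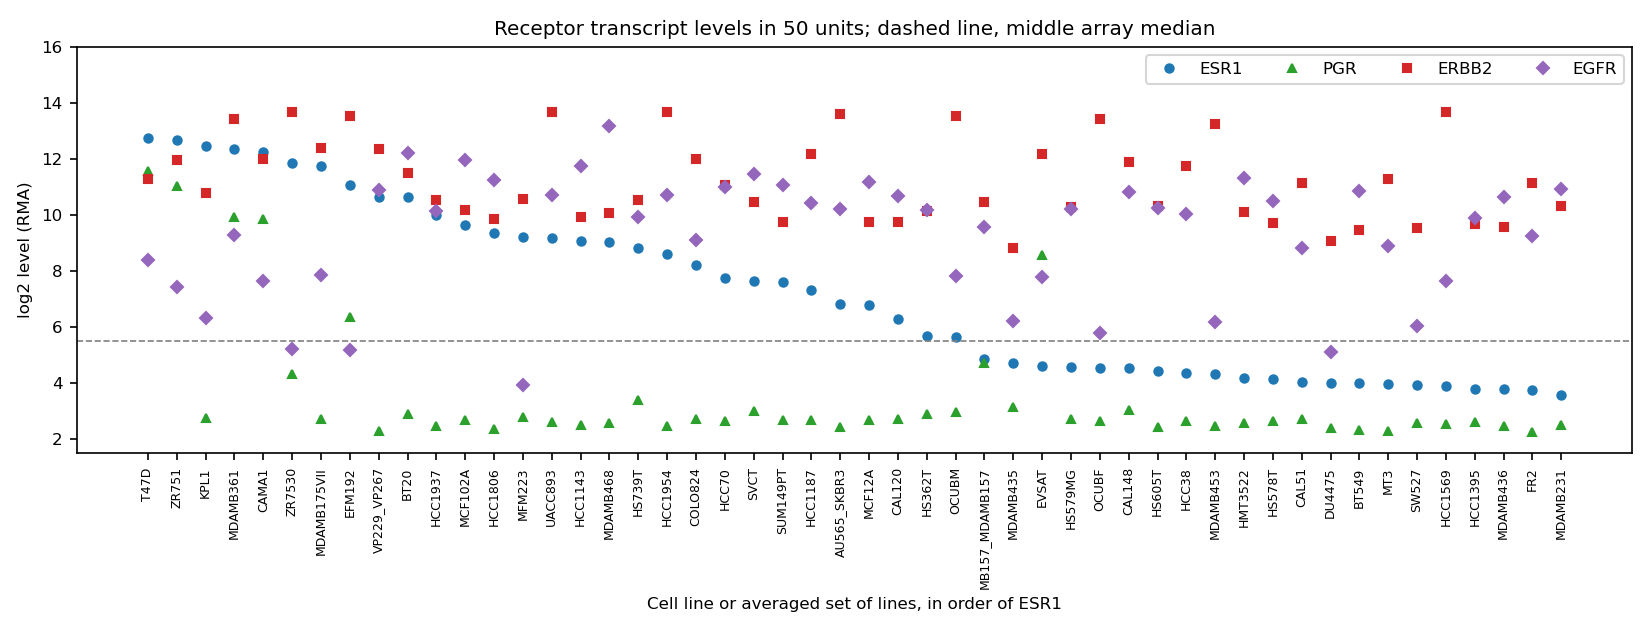
Levels of ESR1, PGR, ERBB2 and EGFR (log2, vertical axis) in the 50 units, ordered by ESR1 along the horizontal axis, 1 point per unit and gene. ESR1 reached 12.73 in T47D and was at background, 5.59 or lower, in 21 units, and the dashed line marks the middle array median.

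Of all detected genes, KRT5, a keratin of basal epithelium, had the largest SD across the lines, 4.25, and was highest in HCC1806 at 13.49 and at background in 28 units. Of the mesenchymal list, the receptor kinase AXL had an SD of 4.15 and a peak in MDAMB231 at 13.45, the caveolar protein CAV1 3.98 with a peak in HS578T, and the matrix protein SPARC 3.69. AGR2, a chaperone of luminal cells, had an SD of 4.13 with its peak in T47D at 13.75, RAB25, a regulator of epithelial vesicle traffic, 3.87, ESRP1, an epithelial splicing factor, 3.73, and FXYD3, a regulator of the sodium pump, 3.71. The mammary secretory protein SCGB2A2 had an SD of 3.74 and was highest in ZR7530 at 13.65, and the calgranulin S100A8 an SD of 3.81 with its peak in MDAMB468 at 13.73. LDHB, a lactate dehydrogenase subunit, was highest in SUM149PT at 13.53 and at background in 9 units, and GSTP1, a glutathione transferase, was highest in CAL51 at 13.90 and at background in 11 units. The gap junction gene GJA1 was highest in BT549 at 13.04, the protease KLK5 in HCC1937 at 13.73, and TSPYL5 in HCC38 at 12.41. Of the 14650 detected genes, 5003 had an SD of at least 1, which is 34.2%, and 188 had an SD of at least 3. The median SD was 0.71 across units and 0.43 within the sets of common origin, and 13196 genes varied more between units than within those sets. The SD was used as a rule of size, with no test. At an SD of at least 1.5, 2885 genes remained.

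Members of gene lists of breast cell identity varied together across the units. The stromal list of collagens and matrix genes was far higher in 5 units than in the rest, HS579MG at 7.87, HS362T at 7.85, HS605T at 7.80, HS739T at 7.79 and HS578T at 7.61, followed by FR2 at 5.19, where a score is the mean distance of the members from their medians in log2 units. Its members COL1A2, a fibrillar collagen, and PDGFRA, chosen as an example after its values were seen, were highest in HS362T at 14.09 and 12.80, and POSTN and LUM, secreted matrix proteins, in HS578T at 13.33 and 12.63. HS579MG, HS362T, HS605T and HS739T, called the 4 Hs lines here, also had the lowest epithelial scores of all units, with HS605T at -5.69. The mesenchymal list was highest in the same 4 lines and HS578T, which scored 3.73, and lowest in T47D at -4.28. The epithelial list was highest in HCC70 at 0.95. The luminal list, with AGR2, the lineage factor FOXA1 and ERBB3, was highest in MDAMB175VII at 3.14 and ZR7530 at 3.06 and lowest in HS605T at -2.51. Estrogen target genes, among them PGR, IGFBP4 and ABAT, were highest in ZR751 at 2.91, T47D at 2.86 and MDAMB361 at 2.58. The basal list, with KRT5, the desmosomal gene DSC3 and TRIM29 among its members, was highest in MCF102A at 4.43, then in HCC1806 and SUM149PT. Inside the averaged sets, MDAMB435S had a lower epithelial score than HS605T, -5.85, EFM192C a lower mesenchymal score than T47D, -4.71, and MDAMB157 a lower luminal score than HS605T, -2.57. The SD of the score was 2.61 for stromal, 2.66 for mesenchymal, 2.42 for epithelial, 1.89 for basal, 1.76 for luminal and 0.89 for estrogen targets, and each list had a permutation p of 0.0001, the smallest that 10000 permutations can give, and an adjusted p of 0.00013 over 30 lists. Each was wider than all of 10000 random lists of genes of like level.

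Other pathways also moved as groups. Interferon-induced antiviral genes, among them IFI44, IFI27 and XAF1, were highest in HCC1187 at 3.49 and HCC1937 at 3.41 and lowest in EVSAT at -2.57, with a score SD of 1.49, while the line EFM192B alone scored 3.76. Genes of MHC class II antigen presentation, HLA-DRA, CD74 and HLA-DMB among them, were highest in MDAMB231 at 4.28, HCC70 at 4.18 and MDAMB435 at 4.17 (SD 1.39), and in that set MDAMB435S alone scored 6.17, M4A4 4.84 and NM2C5 1.49. The apocrine and androgen-regulated list with the secretory proteins SCGB2A2, SCGB1D2 and PIP was highest in EVSAT at 4.64 and MDAMB361 at 4.56 (SD 1.74). Cancer testis antigens, normally confined to germ cells, were highest in UACC893 at 5.81 and MDAMB435 at 4.99 (SD 1.73), with MAGEA12 highest in MDAMB468, PRAME in MFM223 and MAGEA4 in MDAMB436. Targets of the oxidative stress factor NRF2, with the aldo-keto reductases AKR1C1, AKR1C3 and AKR1B10, were highest in HCC1395 at 2.35 and lowest in CAMA1 at -2.10 (SD 1.08). DU4475 had the lowest score for hypoxia-induced genes, -1.81, and for receptors, -2.17. The most variable of the hypoxia genes were EGLN3, ADM and BNIP3 (SD of the score 0.53), and BNIP3, a mitophagy gene, was at background in 2 units, DU4475 among them. Genes of amino acid shortage and endoplasmic reticulum stress, among them VLDLR, the serine synthesis gene PSAT1 and ATF3, were highest in OCUBM at 1.77 (SD 0.59). Cholesterol synthesis genes were highest in DU4475 at 0.96 (SD 0.54), with STARD4 highest in SW527 and DHCR7 in HCC1187. Proliferation genes, CDC20, E2F1 and BIRC5 among them, had an SD of only 0.52 and were lowest in HS362T at -1.76 over units, but the lines EFM192A and VP229 alone scored -2.17 and -1.99. Neighbouring genes of 8p11 were highest in CAL120 at 1.86 and MFM223 at 1.63, with LETM2 and FGFR1 at their peak in CAL120, and lowest in HCC70 at -1.61 (SD 0.60). Those of 11q13, where ANO1, SHANK2 and the cyclin CCND1 lie, were highest in ZR751, then in MDAMB175VII at 1.46 (SD 0.89). The lists of 17q12 (SD 0.94), 9p21 (2.39), receptors (0.90) and tumour suppressors (0.64) also varied. The tumour suppressor list holds all 3 genes of the 9p21 list, and without them, a run chosen after the overlap was seen, its SD was 0.50 and it did not pass (adjusted p = 0.166). Of 30 lists, 26 had an adjusted p under the threshold, 0.00487 for tumour suppressors and 0.00013 for the others named in this paragraph.

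Marker lists of other cell types were tested in the same way. Melanocyte genes stood at 4.70 in MDAMB435, against 1.75 in T47D, with RAB38 at 11.37 and the lineage factor SOX10 at 11.65 in that set, in which M4A4 alone scored 4.98, MDAMB435S 3.11 and NM2C5 more than either (score SD 0.85, adjusted p = 0.0188). Without the MDAMB435 set and MT3 the SD was 0.59 with an adjusted p of 0.909. Intestinal genes stood at 7.71 in MT3, against 2.72 in SW527, with the tetraspanin TSPAN8 at 12.62 in MT3, while CEACAM5 was highest in CAL148 and CDH17 in CAL51 (SD 1.37, adjusted p = 0.00013). The list of contractile genes of myoepithelium and smooth muscle, TAGLN, OXTR and ACTA2 among them, was highest in HS578T at 4.65 (SD 1.27), and keratinocyte differentiation genes, S100A8, S100A9 and IVL among them, in MDAMB175VII at 3.22 (SD 1.39), both with an adjusted p of 0.00013, while EFM192B and VP229 alone scored 3.48 and 3.32 for the latter. Neuroendocrine genes were highest in DU4475 at 3.02, with SCG2 highest in CAL120, INSM1 in MDAMB361 and STMN2 in HS362T (SD 0.74, adjusted p = 0.0188). Markers of blood cells (adjusted p = 0.128), endothelium (0.0741), fat cells (0.226) and liver (0.362) did not vary together past the threshold. Only detected members enter a score, 4 of 10 for blood cells, 8 of 8 for endothelium, 4 of 6 for fat cells and 5 of 8 for liver. Markers above the array median in fewer than 3 units were thus not part of these tests. Single members were nevertheless high in single lines. LAPTM5, a lysosomal gene of blood cells, was highest in MCF12A at 10.62, HCLS1 in HCC1806 at 10.78 and IKZF1 in HCC1187 at 9.97. PECAM1, an endothelial adhesion gene, was highest in HCC1954 at 11.36 and FABP4, a fatty acid carrier of fat cells, in MDAMB175VII at 11.13. CDH5 was highest in BT20 at 8.81, PLIN1 in OCUBF at 7.56, SERPINA1 in T47D at 12.92 and TF, the transferrin gene, in HCC1569 at 12.95. Inside sets, VP229 had 9.59 of CDH5 and 8.43 of PLIN1, VP267 11.65 of FABP4 and HMT3522T42 13.37 of SERPINA1, above those units. The adipocyte list passed with no filter on low values (adjusted p = 0.0307) and the endothelial list without the 4 Hs lines (adjusted p = 0.0276).

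Where the mesenchymal score was high, the epithelial and mesenchymal programmes opposed each other, and the stromal list rose with the mesenchymal one. Among the 34 units of the higher mesenchymal cluster, the stromal and mesenchymal scores rose together (Pearson r = 0.784, p = 1e-05, Spearman rho = 0.820, p = 1e-05, adjusted p = 0.000187). In the same cluster the luminal score was lower where the mesenchymal score was higher (r = -0.695, rho = -0.730, p = 1e-05 for both, adjusted p = 0.000187, n = 34). Among 17 units with a low epithelial and a high mesenchymal score, these opposed each other (r = -0.802, p = 0.00012, rho = -0.772, p = 0.00046, adjusted p = 0.00168), and so they did among the 17 units high in both (r = -0.696, p = 0.00212, rho = -0.677, p = 0.00383, adjusted p = 0.0170). Luminal and epithelial scores rose together among the 33 units with a high epithelial score (r = 0.526, p = 0.00145, rho = 0.529, p = 0.00159, adjusted p = 0.0144) and the 17 with a low one (r = 0.666, p = 0.00329, rho = 0.826, p = 9e-05, adjusted p = 0.0230). Over all 50 units the luminal score fell with the stromal score (r = -0.600, p = 1e-05, rho = -0.632, p = 3e-05, adjusted p = 0.000187) and with the interferon score (r = -0.442, p = 0.00154, rho = -0.438, p = 0.00183, adjusted p = 0.0144). Epithelial and stromal scores opposed each other in the 17 units of the low epithelial cluster (r = -0.633, p = 0.0075, rho = -0.679, p = 0.00366, adjusted p = 0.0467). In the 16 units with a low mesenchymal score, all high in the epithelial score, the relations with the mesenchymal score did not pass. There r was 0.429 for the epithelial score (rho = 0.459, adjusted p = 0.239), 0.047 for the stromal (adjusted p = 0.921) and 0.267 for the luminal score (adjusted p = 0.542).

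In this family 8 scores made 28 pairs and 56 testable relations, of which 9 passed with Pearson r and 11 with Spearman rho. Where a score split into separate clusters, no pooled r is given. All p-values are 2-sided permutation p-values, and 1e-05 is the smallest that 100000 permutations can give. Without the 2 units farthest from the median of the first score, r was 0.785 for mesenchymal and stromal, -0.656 for luminal and mesenchymal, -0.657 and -0.707 for the epithelial and mesenchymal pairs in the order given, 0.528 for luminal and epithelial in the high cluster, -0.600 for luminal and stromal, -0.414 for luminal and interferon, and -0.631 for epithelial and stromal. For luminal and epithelial in the low cluster it was 0.492 with p = 0.0611, so the call by r rests on CAL51 and SW527, while rho over all 17 units was 0.826. By rank alone, basal and epithelial scores rose together in the low epithelial cluster (rho = 0.733, adjusted p = 0.00989, r = 0.574, adjusted p = 0.0900, n = 17), and stromal and interferon scores over all 50 units (rho = 0.427, adjusted p = 0.0134, r = 0.182, adjusted p = 0.387). With all 58 lines as units the clusters changed, and the relation of epithelial and mesenchymal scores in the cluster high in both turned to r = 0.351 with an adjusted p of 0.660, while that in the cluster low and high was -0.468 (adjusted p = 0.219). Without the 3 widest arrays (HS362T, MB157 and EFM192A) both missed the threshold (r = -0.526 and -0.634, adjusted p = 0.0780 and 0.0596). Without the 4 Hs lines luminal and epithelial scores in the low cluster did (r = 0.535, adjusted p = 0.214), and epithelial and stromal scores did under each of 4 alternatives (r from -0.604 to -0.441, adjusted p from 0.0719 to 0.306).

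**Figure D2:**
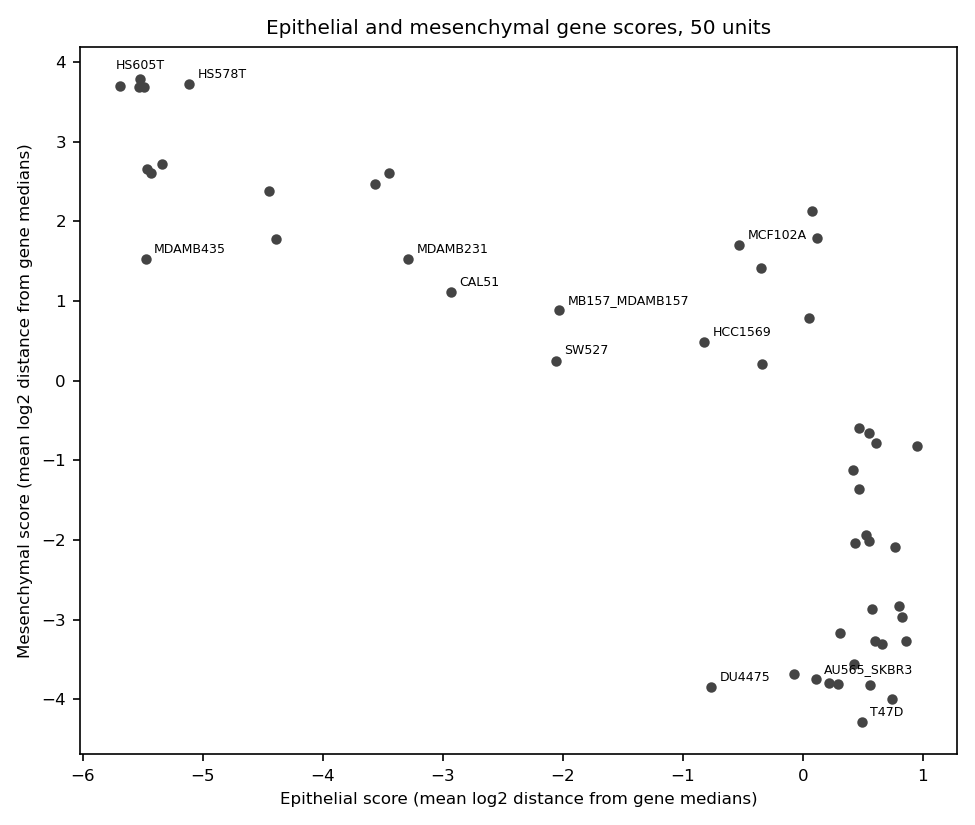
Mesenchymal score (vertical axis) against epithelial score (horizontal axis), both as mean log2 distance from gene medians, 1 point for each of the 50 units. T47D lies lowest on the mesenchymal axis at -4.28 and HS605T lowest on the epithelial axis at -5.69.

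Among the genes that rose with ESR1, the estrogen receptor, were 3 of the 11 estrogen targets of the fixed list, GREB1, PGR and ABAT. ESR1 formed a low cluster of 21 units at 4.18 ± 0.36 (SD), all at background, and a high cluster of 29 units at 9.34 ± 2.18, so its slope was taken within the clusters. Since the low units varied little and at background, the slopes rest mainly on the 29 high units. GREB1, an estrogen-induced growth gene, rose by 0.66 ± 0.10 log2 units (SE, n = 50 here and below) for each log2 unit of ESR1, PGR by 0.84 ± 0.16, and the aminotransferase ABAT by 0.80 ± 0.13. CBFA2T3, a transcriptional corepressor, rose by 0.80 ± 0.12, CCDC170, which lies beside ESR1 in the genome, by 0.45 ± 0.07, CT62 by 0.42 ± 0.06 and the pseudogene CYP2B7P by 0.74 ± 0.13. C5AR2, a complement receptor, KCNF1, a potassium channel gene, and ALG1L1P completed the 10 with the smallest p. Of the 10 declines with the smallest p, the largest was that of SDHAF3, an assembly factor of succinate dehydrogenase, which fell by 0.92 ± 0.18. CTSC, a lysosomal protease, fell by 0.62 ± 0.14, OAF by 0.45 ± 0.10, the DNA damage gene GADD45A by 0.30 ± 0.07, the glucose metabolism gene PGM1 by 0.30 ± 0.07 and the transcription factors NFIL3 and BACH1 by 0.28 ± 0.07 and 0.19 ± 0.04. USP25, PHC2 and RHD made up the rest.

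With limma, 87 genes rose with ESR1 and 35 fell among 14649 tested, and 2374 had an unadjusted p under 0.05. Of 11 estrogen targets, 3 rose and 8 did not pass, and 7 rose when adjusted over the list alone. As a set they were shifted upward (camera adjusted p = 2.37e-08, and adjusted p = 0.00248 with an estimated correlation). Of 13 luminal genes, XBP1 and TFF3, chosen after their values were seen, rose, and 12 did when adjusted over the list alone (adjusted p = 2.1e-10, and adjusted p = 0.0316 with an estimated correlation). No mesenchymal gene of 14 passed over all genes and 8 fell when adjusted over the list alone (adjusted p = 2.21e-09, but adjusted p = 0.169 with an estimated correlation). Of 7 genes of 11q13, none passed over all genes and 5 rose over the list alone (adjusted p = 0.000247, but adjusted p = 0.123 with an estimated correlation). The epithelial, stromal, interferon, hypoxia and apocrine sets also passed with the preset correlation and not with the estimated one, where their adjusted p was 0.385, 0.385, 0.45, 0.353 and 0.29. Without the 4 Hs lines, which together with HS578T have the highest stromal and mesenchymal scores, 54 genes rose and 20 fell, and with all 58 lines as units 279 rose and 134 fell. With the mean of probe sets 148 rose, and leaving out 3 wide arrays or regrouping the pairs of like names left 21 and 19 that fell. The declines of BACH1, CTSC, GADD45A, NFIL3 and OAF each missed the threshold under at least 1 alternative. There BACH1 fell by 0.19, CTSC fell by 0.70 with the mean of probe sets and by 0.44 with the regrouped pairs, and NFIL3 fell by 0.26 without 3 wide arrays and by 0.27 without the 4 Hs lines. GADD45A fell by 0.19 with 58 lines and by 0.23 with the regrouped pairs, and OAF fell by 0.36 with the regrouped pairs.

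Of the 10 genes that rose with ERBB2, the HER2 receptor, with the smallest adjusted p, 3 were its neighbours in 17q12. GRB7, an adaptor of growth factor receptors, rose by 0.96 ± 0.09 for each log2 unit of ERBB2, PGAP3, an enzyme of lipid anchor remodelling, by 0.84 ± 0.09, and MIEN1, which lies between ERBB2 and GRB7, by 0.70 ± 0.09. The aldehyde dehydrogenase ALDH3B2 rose by 1.72 ± 0.23, the semaphorin SEMA4A by 1.13 ± 0.14, the lipid flippase ATP8A1 by 1.02 ± 0.14 and the cation channel TRPM4 by 0.62 ± 0.08, with CYB561, CACFD1 and PDXDC1 rising by 0.40, 0.35 and 0.31. FOSL1, a component of the AP-1 factor, fell by 1.38 ± 0.20, the membrane protein EMP3 by 1.32 ± 0.21, the noncoding RNA LINC00941 by 1.28 ± 0.17, the phosphodiesterase PDE4A by 0.97 ± 0.14 and DYRK3, a kinase, by 0.75 ± 0.11. DPYSL2, REP15, DPY19L1, PPP1R18 and PYROXD1 fell by 0.71, 0.58, 0.57, 0.55 and 0.25. With the mean of all probe sets PYROXD1 fell by 0.12 and did not pass (adjusted p = 0.0576). Among receptors 4 of 12 rose, which were PRLR, ERBB3, ERBB4 and FGFR4, and MET fell.

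With limma, 1807 genes rose with ERBB2 and 1312 fell among 14649 tested, and 4970 had an unadjusted p under 0.05. ERBB2 formed no separate clusters, so its slope spans all units, and its count cannot be set against those of ESR1 and CDH1, taken within clusters. Of 12 neighbours in 17q12, 10 rose and PNMT and CDK12 did not pass, and 11 rose when adjusted over the list alone. Of 17 epithelial genes 15 rose, among them RAB25 by 1.49 ± 0.31, ESRP1 by 1.23 ± 0.31 and CDH1 by 0.88 ± 0.29, and 16 over the list alone. Of 13 luminal genes 11 rose, with AGR2 by 1.53 ± 0.33 and FOXA1 by 1.34 ± 0.27, and 11 over the list alone. Of 14 mesenchymal genes 13 fell, with AXL by 1.65 ± 0.33 and CAV1 by 1.54 ± 0.32, and 14 over the list alone. Of 13 stromal genes 3 fell and 11 over the list alone. Of 9 apocrine genes 5 rose, with SCGB2A2 by 1.59 ± 0.28 and PIP by 1.41 ± 0.26, and 6 over the list alone. All 6 of these sets passed with camera's preset correlation and none with an estimated one, where the adjusted p was 0.0726 for 17q12, luminal, mesenchymal and apocrine genes, 0.18 for epithelial and 0.532 for stromal genes. With the epithelial score and its cluster in the fit, 242 of the 3119 genes stayed past the threshold, while the slopes kept a median of 61.3% of their size. By list, the called members kept a median of -5.62% for epithelial genes, 4.17% for stromal, 36.5% for luminal, 41.3% for mesenchymal and 74.3% for apocrine genes.

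In the 10 units with the highest ERBB2, its neighbours in 17q12 were high to differing degrees. Without ERBB2 itself, the 12 neighbours scored 3.51 in UACC893, 2.53 in AU565_SKBR3, 2.43 in HCC1954 and 2.34 in EFM192, but 1.14 in ZR7530, 0.92 in MDAMB453 and 0.44 in HCC1569. ERBB2 itself hardly differed between UACC893 at 13.69 and HCC1569 and ZR7530 at 13.68, so the order of these units for ERBB2 carries little weight. DU4475, with an ERBB2 level of only 9.07, scored 1.59. UACC893 had the highest GRB7 at 12.50, ORMDL3, a regulator of sphingolipid synthesis, at 13.20, the proteasome gene PSMD3 at 13.43 and the mediator gene MED24 at 11.81. HCC1954 had the highest STARD3, a cholesterol carrier, at 11.99, MIEN1 at 13.42 and the sarcomere gene TCAP at 8.86, and ZR7530 the highest PGAP3 of the units at 12.09, with 12.50 in the line EFM192A. GSDMB, a pore-forming gasdermin, was highest in AU565_SKBR3 at 12.78 and MED1 in EFM192 at 12.24, while CDK12, a kinase of transcription elongation, was highest in UACC893 at 12.15. PNMT, the enzyme that makes adrenaline, was highest in DU4475 at 12.09. Over all 50 units ERBB2 was correlated with GRB7 (r = 0.839, rho = 0.760, p = 1e-05 for both, adjusted p = 7.5e-05), ORMDL3 (r = 0.691, rho = 0.675, p = 1e-05 for both, adjusted p = 7.5e-05), PSMD3 (r = 0.508, p = 0.00016, rho = 0.410, p = 0.00358, adjusted p = 0.00048) and MED24 (r = 0.404, p = 0.003, rho = 0.319, p = 0.0245, adjusted p = 0.00716). Without UACC893 and HCC1569, the 2 units farthest from the ERBB2 median, r was 0.823, 0.689, 0.479 and 0.386.

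For the neighbours that formed clusters, only r within a cluster is given. PGAP3 followed ERBB2 in its 42 lower units (r = 0.554, p = 0.00015, rho = 0.556, p = 0.00023, adjusted p = 0.00048), TCAP in its 47 lower units (r = 0.546, p = 6e-05, rho = 0.413, p = 0.00445, adjusted p = 0.0003) and MIEN1 in its 10 higher units (r = 0.813, p = 0.00334, rho = 0.754, p = 0.0148, adjusted p = 0.00716). Without the 2 farthest units r was 0.670, 0.468 and 0.808. MIEN1 in its 40 lower units gave r = 0.353 (p = 0.0255, rho = 0.271, p = 0.0899, adjusted p = 0.0478), and 0.210 with p = 0.206 without the 2 farthest units, so the call by r rests on MDAMB453 and MDAMB175VII, and without the 4 Hs lines r was 0.348 with an adjusted p of 0.0561. Of 15 relations tested 8 passed. GSDMB in its lower units and CDK12 did not (adjusted p = 0.0521 for both), nor did PNMT (0.245), MED1 in its lower units (0.315) and STARD3 in either cluster (0.193 and 0.315), nor PGAP3 in its 8 higher units (exact permutation, adjusted p = 0.117). The split removes the contrast between clusters, so r within them cannot show whether a gene is high where ERBB2 is high. In the limma fit over all units STARD3 rose by 0.60 ± 0.10 for each log2 unit of ERBB2, GSDMB by 0.67 ± 0.13 and MED1 by 0.20 ± 0.06. The lower units of STARD3 passed under 4 alternatives (adjusted p from 0.0027 to 0.00497), CDK12 under 4 (0.0085 to 0.0449) and GSDMB under 3 (0.00832 to 0.0426), and PGAP3 in its higher units without 3 wide arrays (adjusted p = 0.00605).

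**Figure D3:**
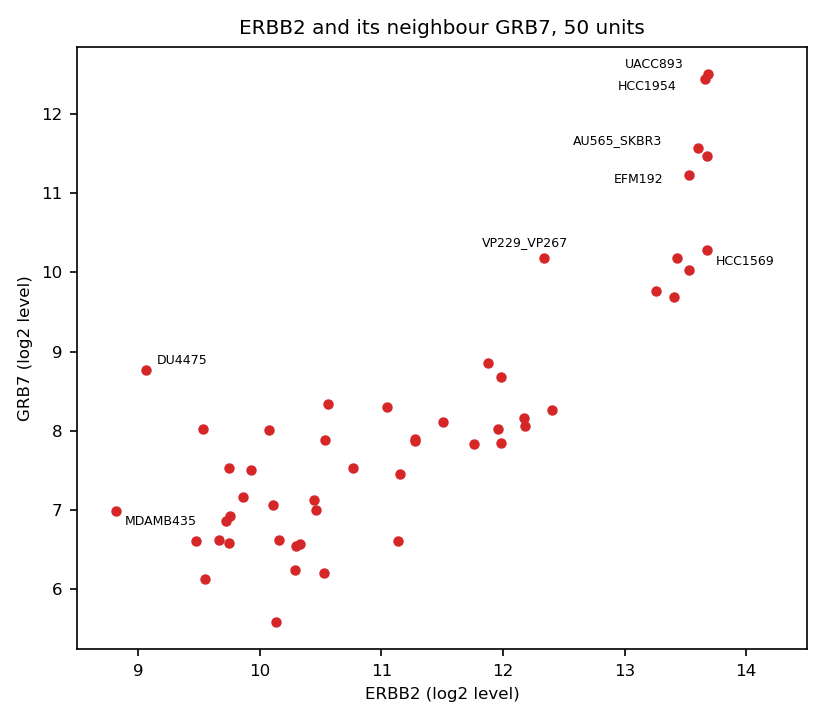
Level of GRB7 (log2, vertical axis) against ERBB2 (log2, horizontal axis), 1 point for each of the 50 units. UACC893 lies highest at 13.69 for ERBB2 and 12.50 for GRB7.

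CDH1, the adhesion protein E-cadherin that joins epithelial cells, separated 17 units at 6.12 ± 2.12 (SD), of which 9 were at background, from 33 units at 12.33 ± 0.86, and 10 of 16 other epithelial genes rose with it within these clusters. CDH1 varied more in the 17 low units, from 3.93 to 9.65, so the slopes rest more on these. The lowest of the high units stood at 9.99, so the clusters nearly touch, and the low one mixes units at background with units that express CDH1. SCNN1A, an epithelial sodium channel, rose by 1.26 ± 0.24 for each log2 unit of CDH1, MAL2, a gene of apical transport, by 1.04 ± 0.20, GALNT3, which starts O-glycan chains, by 1.03 ± 0.18, PROM2 by 0.89 ± 0.18, the vesicle fusion gene VAMP8 by 0.89 ± 0.17, the tight junction gene CLDN7 by 0.88 ± 0.17 and the protease inhibitor SPINT2 by 0.79 ± 0.13. MIR200CHG, the host gene of microRNAs that repress ZEB1, rose by 0.60 ± 0.12, CHMP4C and MAP3K21 by 0.68. Among the genes that fell, DACT1 fell by 1.23 ± 0.23, the collagen gene COL1A2 by 1.19 ± 0.23, the mesenchymal factor PRRX1 by 1.15 ± 0.22, LDB2 by 0.86 ± 0.17 and PCOLCE, which processes collagen, by 0.75 ± 0.14. SMIM10, ALPK2, RCN3 and DENND5A fell by 0.91, 0.68, 0.55 and 0.38, and the matrix protease MMP3 also fell (adjusted p = 0.00606).

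With limma, 71 genes rose with CDH1 and 45 fell among 14649 tested, and 1851 had an unadjusted p under 0.05. Of 16 epithelial genes other than CDH1, 10 rose, RAB25, ESRP1, CLDN7 and MAL2 among them, and 14 rose when adjusted over the list alone (camera adjusted p = 4.87e-21, and adjusted p = 0.0163 with an estimated correlation). Of 13 stromal genes, COL1A2 fell and 9 did over the list alone (adjusted p = 5.54e-12, but adjusted p = 0.115 with an estimated correlation). Of 14 mesenchymal genes, ZEB1, a repressor of E-cadherin chosen after its values were seen, fell by 0.97 ± 0.24, and 7 did over the list alone (adjusted p = 2.24e-09, but adjusted p = 0.179 with an estimated correlation). The luminal, basal, apocrine, intestinal, keratinocyte, neuroendocrine and smooth muscle sets passed with the preset correlation and not with the estimated one (adjusted p = 0.386 for keratinocyte genes and 0.189 for each of the others). With all 58 lines as units, limma gave 2 genes that rose and 0 that fell, beside 1229 with an unadjusted p under 0.05, and none of the 20 genes named here passed. Their slopes were smaller to differing degrees, among them 1.09 for SCNN1A, 0.83 for GALNT3, 0.75 for VAMP8 and 0.70 for SPINT2, while LDB2 fell by 0.76 and DENND5A fell by 0.10. With the stricter rule for clusters CDH1 was not split, and 1861 genes rose and 1444 fell. Without the 4 Hs lines 44 rose and 13 fell, and 14 of the 20 genes did not pass, all but SPINT2, VAMP8, CLDN7, CHMP4C, MMP3 and PCOLCE. There SCNN1A rose by only 0.64 (adjusted p = 0.333), MAL2 by 0.59 (adjusted p = 0.17) and MAP3K21 by 0.35 (adjusted p = 0.257). DACT1 then fell by 0.53 (adjusted p = 0.398), COL1A2 fell by 0.65 (adjusted p = 0.224) and LDB2 fell by 0.38 (adjusted p = 0.324), while ALPK2, RCN3 and SMIM10 fell by 0.30, 0.30 and 0.59. GALNT3, PROM2 and MIR200CHG rose by 0.76, 0.63 and 0.51, and PRRX1 and DENND5A fell by 0.83 and 0.30. Without the MDAMB435 set and MT3 18 rose and 11 fell, and CLDN7, CHMP4C, MIR200CHG, DENND5A, RCN3 and SMIM10 did not pass (adjusted p from 0.0556 to 0.09), with slopes of 0.77, 0.61 and 0.54 for the first 3, while the others fell by 0.24, 0.51 and 0.88. Without 3 wide arrays 26 rose and 18 fell, and SMIM10 fell by 0.92 and did not pass (adjusted p = 0.0524).

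MKI67, the antigen of dividing cells, was followed by genes of DNA replication and mitosis. Over units it ran only from 8.13 in HS362T to 11.77 in HCC1806, with 7.48 in the line VP229. DEPDC1B rose by 0.87 ± 0.11 for each log2 unit of MKI67, the mitotic kinesins KIF15, KIF18B and KIF20B by 0.76 ± 0.10, 0.67 ± 0.09 and 0.63 ± 0.09, the centriole kinase PLK4 by 0.63 ± 0.08, the replication factor ATAD5 by 0.73 ± 0.10, the lamin gene LMNB1 by 0.53 ± 0.07 and the spindle factor TPX2 by 0.47 ± 0.07. CDCA4 rose by 0.45 ± 0.06 and HNRNPD by 0.28 ± 0.04. VASN, a cell surface binder of TGF-beta, fell by 0.82 ± 0.17, ZNF506 by 0.71 ± 0.15, SERF2 by 0.55 ± 0.10, FBXW8 by 0.53 ± 0.11 and the lysosomal ceramidase ASAH1 by 0.41 ± 0.09. RNF103, ZER1, SERINC1, ERLEC1 and TMEM59 fell by 0.46, 0.39, 0.33, 0.31 and 0.23. With limma, 628 genes rose and 226 fell among 14649 tested, and 2807 had an unadjusted p under 0.05. All 14 proliferation genes rose, with CDC20 by 0.64 ± 0.11, BIRC5 by 0.53 ± 0.12 and E2F1 by 0.44 ± 0.13, also over the list alone (camera adjusted p = 2.79e-22, and adjusted p = 0.00189 with an estimated correlation). The basal list with 1 of 9 genes and the stromal list with 0 of 13 passed in camera, upward and downward (adjusted p = 0.00725 for both), but not with an estimated correlation (adjusted p = 0.905 for both). Over the 4 fits the camera calls that held with an estimated correlation were estrogen targets and luminal genes for ESR1, epithelial genes for CDH1 and proliferation genes for MKI67. Without the 4 Hs lines, whose stromal scores with that of HS578T are the highest, 102 genes rose and 24 fell, and SERINC1, TMEM59, ERLEC1 and VASN fell by 0.24, 0.20, 0.26 and 0.49 and did not pass. With array quality as a term 301 rose and 59 fell. Without 3 wide arrays the counts were 313 and 68, and with all 58 lines as units 983 and 505.

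At 9p21, where MTAP, CDKN2A and CDKN2B lie side by side, 11 units had CDKN2A at background level, below the 95th percentile of the viral probe sets of 5.59. MTAP, an enzyme of methionine salvage, was low in 6 units, HCC1395, MCF102A, HCC38, SUM149PT, MDAMB231 and KPL1, at 2.39 ± 0.23 (SD) against 9.63 ± 0.69 in the other 44. CDKN2A, which encodes inhibitors of the cell cycle, was low in those 6 units and also in HS578T, MCF12A, HCC1806, MT3 and BT20, where MTAP was high. The 11 units had a CDKN2A level of 3.13 ± 0.69 against 10.35 ± 1.27 in the other 39. HCC70 had the highest level of all 3 genes, 12.87 for CDKN2A, 11.42 for CDKN2B and 11.11 for MTAP. Among the 39 units with high CDKN2A, it was correlated with CDKN2B (r = 0.601, p = 0.0001, rho = 0.610, p = 0.0001, adjusted p = 0.0006) and with MTAP (r = 0.452, p = 0.0041, rho = 0.440, p = 0.00557, adjusted p = 0.0123), and without the 2 farthest units r was 0.566 and 0.424. Of 6 relations tested, these 2 passed. CDKN2B and MTAP did not pass in the 44 units with high MTAP (r = 0.126, adjusted p = 0.622), nor in the 6 with low MTAP (r = 0.943, rho = 0.257, exact permutation p = 0.129 and 0.658). The split leaves only background levels of MTAP in the 6, so r there cannot show whether the genes are low together. CDKN2B was at background in those units, from 3.16 to 3.26, except KPL1 at 8.67. It was also at background in the other units with low CDKN2A, except HS578T at 10.01, and in MFM223 and MDAMB361, where CDKN2A was high.

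**Figure D4:**
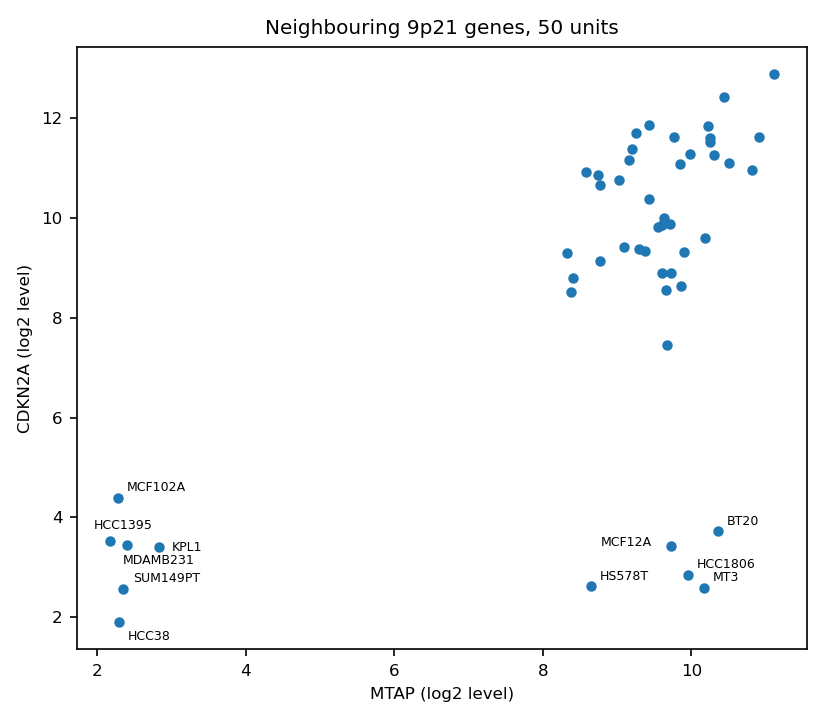
Level of CDKN2A (log2, vertical axis) against MTAP (log2, horizontal axis), 1 point for each of the 50 units. The 6 units low for MTAP have a mean MTAP level of 2.39 and are low for CDKN2A too.

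Other tumour suppressor transcripts were low or at background in 1 or more units. Folds against background, levels up to 5.59, are lower bounds. RB1, the retinoblastoma gene, had a median of 10.33 and was low in 7 units, at background and thus at least 26.7-fold lower in DU4475, MDAMB468, CAL148 and BT549, 14.9-fold lower in COLO824, and less so in MDAMB436 and OCUBM. SMAD4, a mediator of TGF-beta signals, was at least 44.5-fold lower in MDAMB468 and 13.8-fold lower in SW527, with AU565_SKBR3 and MDAMB436 nearer the median. MAP2K4, a stress kinase, was at least 30.2-fold lower in DU4475, NF2, which encodes merlin, at background in MDAMB436 and 6.19-fold lower in MDAMB231, and STK11, the kinase LKB1, at least 38.2-fold lower in SUM149PT. ARID1A, a chromatin remodeller, was 3.39-fold lower in T47D. CDH1 was low in 12 units, among them HS362T, MDAMB436, AU565_SKBR3 and FR2, and CDKN2A and MTAP in 7 and 6 by this rule. NF1, APC and TSC1 had no unit this low. For CDKN2B the rule could find none, since its limit lay at 0.21, while 11 units had CDKN2B at background. In all, 41 pairs of unit and gene in 9 of 13 genes were more than 3 scaled median absolute deviations and at least 1.5 log2 units below the gene's median, a rule of size with no test. MDAMB436 was low for 4 of the genes and SUM149PT for 3.

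Some genes were high in 1 unit alone. ASCL5, a transcription factor, reached 12.44 in DU4475, at least 115-fold above the next unit, which was at background, PNMA5 13.03 in HCC1187, 94.9-fold above, and the intestinal lectin LGALS4 12.81 in MT3, 75.3-fold above. The airway secretory protein SCGB1A1 reached 12.49 in HCC1937, the tyrosine catabolic enzyme TAT 12.30 in MDAMB361 and the tear protein LACRT 13.72 in UACC893. GAS2 was highest in HCC1569, the amino acid transporter SLC1A7 in MDAMB453, C1orf105 in COLO824 and IRF4, a transcription factor of lymphocytes and melanocytes, in MDAMB435 at 10.98. The kidney cotransporter SLC12A3 was highest in CAL51, the urothelial gene UPK3B in MDAMB175VII, ANO7 in MFM223, SLITRK2 in BT549 and the pregnancy-specific glycoprotein PSG2 in CAL120 at 10.95. By the rule of a gap of at least 3 log2 units to every other unit, 83 genes in 30 units were of this kind, 20 of them in DU4475, 6 in MT3 and 5 in HCC1187. No replicate tests such a gap, and normal values simulated with the SD of each gene gave 72 genes by the same rule. The simulated values had a normal shape without a floor, so the 72 do not say how many of the 83 are chance. The count was 271 at a gap of at least 2, 279 with no filter on low values and 2 with a filter at the 75th percentile. With all 58 lines apart the gap of SLC12A3 fell to 1.14, since EFM192B reached 11.25, that of LGALS4 was 5.46 in place of 6.23 and that of SCGB1A1 4.86 in place of 5.98. With the mean of probe sets the gap of ANO7 was 2.85, under the rule. The gap of SLC12A3 was 3.83 without 3 wide arrays, and that of IRF4 3.03 with the pairs of like names regrouped.

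Lines of common origin resembled each other, though they differed in single genes by large factors. Over 10 pairs of common origin the mean r across detected genes was 0.613, and over 7 pairs that share a name, 5 of which are among those 10, it was 0.529, against a median of -0.0378 and a 95th percentile of 0.316 over the other pairs (1-sided permutation p = 1e-05 for both, the smallest that 100000 permutations can give). These r are across genes, which are not independent replicates. NM2C5 and M4A4, derivatives of MDAMB435, were the closest of these at 0.913, then SKBR3 and AU565 at 0.799, and OCUBF and OCUBM, which share a name, at 0.739. For 13 of the 14 lines the closest line shared the origin, and for MDAMB157 it was HS578T. Within pairs, SKBR3 and AU565 differed most in the testis antigen CT45A5, 3.59 and 10.81, the GTPase RRAS2 and the WNT receptor FZD6. MDAMB435S had 11.54 of the retinal dehydrogenase ALDH1A3 and 12.01 of the antigen MAGEC2 where NM2C5 had 2.95 and 3.42, while NM2C5 had 12.32 of the pigment enzyme TYRP1 where MDAMB435S had 3.78. MDAMB435S also exceeded M4A4 in MAGEC2, ALDH1A3 and POSTN. NM2C5 and M4A4 differed in HLA-DRB3, TTC28-AS1 and TSPAN7. EFM192A had 12.19 of the transporter ABCC4 where EFM192C had 3.97, more ADGRF1 and less CXCL14. EFM192B had more MT1G, IGFL1 and SLC12A3 than EFM192A, and more LDHB and IGF2 and less AFF3 than EFM192C. VP229 had 12.23 of CYP2B7P where VP267 had 3.73, and VP267 more of PLAT and CNTN1. The HMT3522 lines T42 and S1 differed in MRFAP1L1, COL5A1 and GNB4, each higher in S1. OCUBF had 12.07 of the actin capping gene CAPZA1 where OCUBM had 3.02, and OCUBF more TCEAL9 and less DUSP3. ZR751 and ZR7530, at r = 0.370, differed in HOXB2, MGST1 and S100A8. MB157 and MDAMB157 had the lowest r of these pairs, 0.327, and the most genes at least 8-fold apart, 777, with the detoxifying enzyme MGST1 at 12.43 and 2.41, the stem cell marker PROM1 at 13.29 and 3.58, and the collagen gene COL3A1 at 3.37 and 12.87. Pairs of common origin differed at least 2-fold in 793 genes, for NM2C5 and M4A4, to 3740, for VP267 and VP229, against a median of 4715 over the other pairs.

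**Figure D5:**
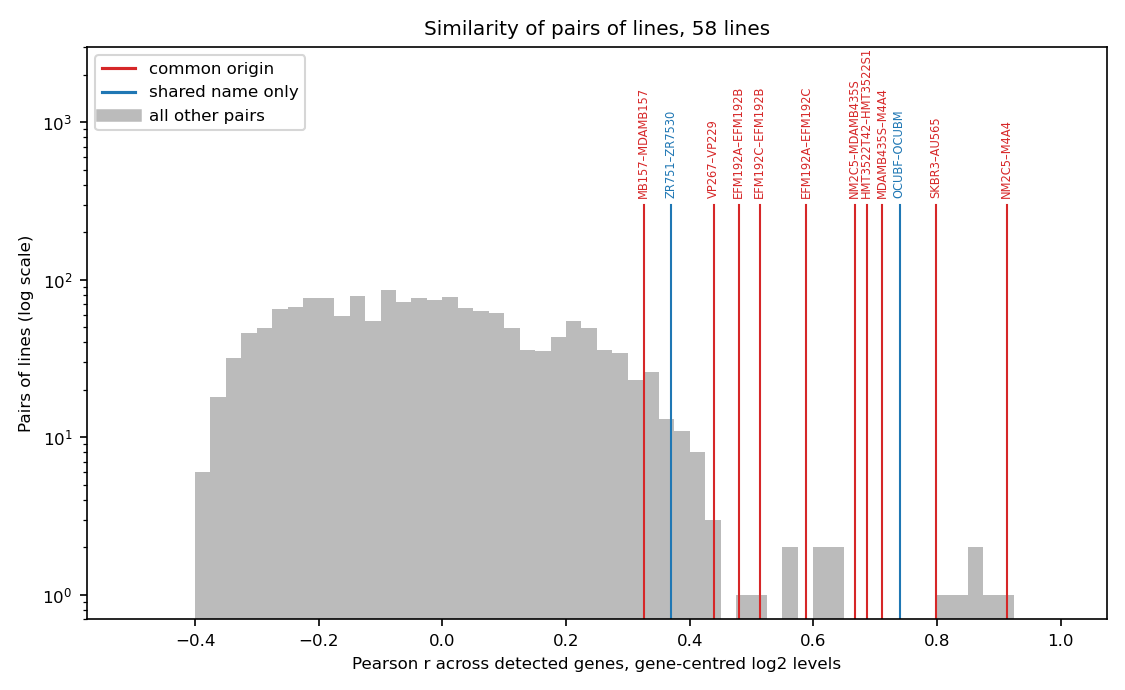
Number of pairs of lines (vertical axis, log scale) by Pearson r across detected genes of gene-centred log2 levels (horizontal axis), with the 10 pairs of common origin and 2 pairs sharing a name only marked by coloured lines. The other pairs have a median r of -0.0378 and a highest r of 0.915.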

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

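The runs without HS362T, HS579MG, HS605T and HS739T, with MB157 and MDAMB157 separate and OCUBF and OCUBM averaged, with a filter at the level of viral probe sets, and with the tumour suppressor list without the 9p21 genes were chosen only after the data were seen. Over 21 settings that changed the data or a choice, 2495 of 2642 alternatives kept the direction and the side of the threshold, or stayed within the spread allowed for values with no test. Of the other 147, 40 concern the leading counts, and of single genes, lists and relations 66 lost their call, 19 gained one, 21 moved and 1 reversed. The mean of probe sets gave 148 genes that rose with ESR1. No filter on low values gave 16 that fell with ESR1 and 279 line-specific genes, and the 75th percentile filter 47 that rose with ESR1 and 2 line-specific genes, since these change which genes are tested. With 58 lines as units, 5 score relations passed, 279 genes rose and 134 fell with ESR1, 983 and 505 with MKI67, and by limma 2 rose and 0 fell with CDH1 (1229 at an unadjusted p under 0.05). There the epithelial and mesenchymal scores in the cluster high in both had r = 0.351. Related lines count more than 1 time in that run, and the cause of each change was not tested. Without the MDAMB435 set and MT3, 18 genes rose and 11 fell with CDH1. Without the 3 widest arrays (HS362T, MB157, EFM192A), 21 fell with ESR1, 26 rose and 18 fell with CDH1, and 313 and 68 with MKI67. Without the 4 Hs lines, 54 and 20 followed ESR1, 44 and 13 CDH1, and 102 and 24 MKI67. With the regrouped pairs 19 fell with ESR1. With array quality as a term, 301 rose and 59 fell with MKI67. That term was the interquartile range of relative log expression alone, since no control probe sets allowed the planned difference between the ends of the GAPDH transcript. The cause was not tested for these 5 settings or for the mean of probe sets. With Ashman's D over 3, CDH1 had no clusters and 1861 genes rose and 1444 fell, since the slope then spans both clusters. Stricter or looser thresholds change counts by construction. At an adjusted p under 0.01, 20 rose and 2 fell with ESR1, 928 and 630 with ERBB2, 11 and 7 with CDH1 and 341 and 42 with MKI67. An SD of at least 1.5 gave 2885 variable genes and a gap of at least 2 gave 271 line-specific genes. Leaving out probe sets marked for cross-hybridisation removed 0 single-gene probe sets, so it tests nothing and is not counted above. Across all settings the mean r of common-origin pairs lay between 0.541 and 0.929 and that of name-sharing pairs between 0.517 and 0.918. The settings include values not centred per gene, where r also reflects the mean levels that all lines share. These ranges can thus not be set against the centred r given above. The viral probe sets, with a 95th percentile of 5.59, lie near the array medians, so levels near or below the median cannot be told from background.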

Other observations

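The tests of array quality for MB157 and MDAMB157 and of the slopes of the 17q12 neighbours were chosen only after the result was seen. Genes of cholesterol synthesis rose with ERBB2, 6 of 11 over all genes and 6 adjusted over the list alone, although the set as a whole did not pass (camera adjusted p = 0.0554, adjusted p = 0.689 with an estimated correlation). The genes named in this paragraph that are not among the 3 most variable of their list were chosen after their values were seen. HMGCS1, an early enzyme of the pathway, rose by 0.31 ± 0.07 log2 units for each unit of ERBB2 (SE, n = 50), DHCR7, which acts at its end, by 0.26 ± 0.09, and IDI1, SQLE, FDPS and MSMO1 by 0.15 to 0.21. Of 11 NRF2 targets 3 fell with ERBB2, also over the list alone, the aldo-keto reductases AKR1C1 by 1.04 ± 0.27 and AKR1C3 by 0.99 ± 0.27 and the cystine transporter SLC7A11 by 0.50 ± 0.12 (adjusted p = 0.117, adjusted p = 0.689 with an estimated correlation). In 11q13, ANO1, a chloride channel, and SHANK2, a scaffold protein, rose by 0.90 ± 0.23 and 0.93 ± 0.18, 2 of 7 genes in both adjustments (adjusted p = 0.134, adjusted p = 0.692 with an estimated correlation). The interferon genes ISG15 and IFIT3 fell by 0.49 ± 0.15 and 0.72 ± 0.20. These are 2 of 17, near the share of 1312 in 14649 over all genes. As a set the interferon genes did not pass (camera adjusted p = 0.0829, adjusted p = 0.817 with an estimated correlation).

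Outside the proliferation list few fixed genes followed MKI67, and those named here were chosen after their values were seen. SFN, a checkpoint protein of epithelium, rose by 1.25 ± 0.39, FKBP5, a chaperone induced by steroid hormones, by 1.09 ± 0.27, the actin regulator CORO1A by 0.70 ± 0.20 and the glycolytic enzyme ENO1 by 0.22 ± 0.05, while HERPUD1, a gene of endoplasmic reticulum stress, fell by 0.43 ± 0.12. The 4 Hs lines resembled each other across genes as closely as lines of common origin, with r from 0.814 to 0.915. Next to them stood HS578T, at r = 0.638 with HS579MG.

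Chance pairing of a gene with the profiles was tested with 100 permutations of the gene's level, within its clusters where it has them. The counts for ESR1, ERBB2 and MKI67 argue against chance pairing among independent units. They do not exclude it, since permutation treats the units as independent while some, such as the 4 Hs lines, resemble each other closely. ESR1 gave 122 genes and its highest permutation 47, with 0 permutations as large. ERBB2 gave 3119 against 61, with 0 as large, and MKI67 854 against 48, with 0 as large. For CDH1, with 116 genes, 1 of the 100 permutations was as large, a share under the 0.05 set beforehand. That permutation gave 277 genes, more than the real pairing, and the reason was not tested. Of the line-specific genes, 0 had another of the same unit within 5 measured genes on the chromosome, where random placements gave a median of 0 and a highest count of 6.

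With the epithelial score and its cluster in the fit, 7.76% of the genes that followed ERBB2 stayed past the threshold. This lies below the bound set beforehand for epithelial identity as the cause. The slopes of all these genes, however, kept a median of 61.3% of their size while the standard errors grew by a median factor of 1.20. How far epithelial identity accounts for them therefore stays open. The called members of the epithelial list kept a median of -5.62%, which the fit goes far to fix since the score is made of them, those of the stromal list 4.17%, the luminal list 36.5%, the mesenchymal list 41.3% and the apocrine list 74.3%. For the 17q12 neighbours the planned test, a count of those past the threshold, fell between the bounds set for either outcome. The slopes of the 10 called genes kept a median of 103%, as high as in 6 of 10000 random sets of the genes that followed ERBB2. The random sets draw genes singly, while the neighbours vary together (camera's estimated correlation 0.43), so this share overstates the weight. By the share of the slope kept, a test chosen after the result was seen, the values argue against epithelial identity as the whole cause of the slopes of the 10 called genes. Past the threshold with those terms were 5 of 12, with slopes of 0.81 for GRB7, 0.87 for PGAP3, 0.79 for MIEN1, 0.64 for ORMDL3 and 0.65 for STARD3, while PSMD3 (0.25 ± 0.06 before, 0.26 ± 0.08 after), MED24 (0.23 ± 0.08, 0.23 ± 0.09), MED1 (0.20 ± 0.06, 0.23 ± 0.08), TCAP (0.16 ± 0.05, 0.16 ± 0.06) and GSDMB (0.67 ± 0.13, 0.57 ± 0.17) lost the call with wider errors. The tables argue against array quality, as 98.7% of all these genes stayed with it as a term. No biological explanation such as a gain of the region was tested, because the series holds no copy numbers.

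MB157 and MDAMB157, reported to come from 1 patient, had the lowest r of all common-origin pairs, 0.327. Whether they differ in origin cannot be told apart from divergence, since their ratio of shared silent genes to that expected by chance lay at percentile 98.8 of all pairs, between the bounds set for either outcome. Array quality stays open too, since 3 other common-origin lines had a wider array than MDAMB157 but none a wider one than MB157, at 0.63. No biological explanation was tested, as the labels give no groups.

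CAMA1 and CAL148, which are not reported to be related, had r = 0.637, rank 14 of 1653 pairs. Of genes silent in one line, 47 were high in the other, against 4 to 86 in the common-origin pairs and a median of 153 over all pairs, and their ratio of shared silent genes, 38.3, lay within the common-origin range of 23.2 to 44.2. By the bounds set beforehand, a common origin or a mixed culture may therefore be a candidate explanation. A gene silent in one line and high in the other goes against a large share of the second line's cells in the first. ESR1 and PGR, chosen after their values were seen, were 12.24 and 9.84 in CAMA1 and at background, 4.51 and 3.01, in CAL148. They argue against a large share of CAMA1 cells in CAL148, while the other direction and a common origin stay open. The ranges of the common-origin pairs are not specific. Of 1641 pairs with neither a reported common origin nor a shared name, 71 lay within both, CAMA1 and CAL148 included. So did CAMA1 with ZR751 (ratio 34.6, 55 genes) and with MDAMB361, and 64 of the 71 had a lower r. Pairs among the 4 Hs lines, which have no reported common origin, reached such values too, with 2 such genes between HS605T and HS739T, so a shared cell identity also stays open and was not tested.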
